A study of Oryza sativa with 12 samples.

How the data were processed

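The samples were 12 RNA libraries from culms of japonica rice (cultivar Zhonghua 11) at the heading stage, in 4 groups of 3. The groups were wild type (WT), a line labelled TAC4-KO, a line labelled TAC4L-KO and a line labelled for both genes (called double-KO here). The titles call the lines knockouts, whereas the genotype field calls them knockdowns. Per the labels' protocols, poly(A) RNA was isolated and fragmented, and first strands were primed with random hexamers. Nothing in the labels says that the replicates of a group were separate plants, so p-values measure only the spread between these samples, which may be technical.

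The deposited table held FPKM values (fragments per kilobase of gene per mega of fragments), 1 column per library and 55986 genes. Per the submitters' processing notes, HISAT2 was used by the authors, with no version. The quantifier, genome build, annotation release and strand setting are not given in the sources used here. Genes were listed by locus identifier, 185 of them outside the numbered chromosomes, with no names, lengths or coordinates. Without strand information or lengths, genes that overlap an antisense partner or share reads with a near-identical copy (among them the light-harvesting, PAL and Rubisco small subunit families) remain uncertain.

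No read counts were used. Depth was inferred from the FPKM values: low values of 1 gene in different libraries are whole multiples of what 1 fragment is worth. Ratios between libraries gave relative depth. The spacing that whole-base-pair gene lengths impose on 993 such genes gave the absolute depth, with a coherence of 0.94 against 0.66 for the best spacing away from its multiples. The inferred depth was 9.8 to 25.2 M fragments (M, mega), a range of 2.58-fold. Gene lengths were not used, so no detection floor in FPKM is given, and a gene at 0 is described only as listed at 0.

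Genes with a mean of at least 1 FPKM over the 12 libraries were tested (19184 genes), on log2(FPKM + 1). All fold changes are on that scale, which understates the change of low genes. The tests used limma 3.58.1 (R 4.3.3) with a trended prior, all 12 libraries in 1 fit and 8 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05 with no fold threshold. The 7 comparisons were each mutant against WT, the double-KO against each single mutant, the single mutants against each other, and the interaction (double-KO minus TAC4-KO minus TAC4L-KO plus WT), which tests whether the double-KO departs from the sum of the single effects. Where 3 libraries face 3, the smallest two-sided p of an exact permutation test is 0.1.

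The 19 gene lists were tested with camera (preset correlation of 0.01 and, beside it, an estimated correlation) and with fry, for lists with at least 3 tested members, with adjustment over the lists of a comparison. The tests of genes and lists, the lists, the rule for naming genes and all but 2 alternatives were fixed before the data were examined. Some tests of explanations, named where they are reported, and 2 alternatives for the overlap of the single mutants were chosen after seeing the data. The rule took both targeted genes, every tested cellulose, brittle culm and secondary wall regulator gene on the lists, the 10 highest and 10 lowest called list genes per main comparison (5 and 5 for the others) whose name the reference placed on the same chromosome and whose groups did not overlap, and up to 4 members of each other list by smallest p. Of the genes picked by this rule, 1 is not reported here. Beyond the lists, at most 2 loci that rose and 2 that fell are given per comparison, by identifier only, chosen after their values were seen.

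Gene names need care. Neither the table nor the reference used here (gene symbols of assembly ASM3414082v1) pairs these locus identifiers with names: 0 of 55986 identifiers matched. Each name was paired with its locus from published rice nomenclature when the lists were written, and a wrong pair would misname a gene. As a check, 124 of the 224 list symbols were found in the reference on the chromosome that the locus identifier states. Another 61 were not found, 36 were family names that were not looked up, and 3 (LPA1, UBQ5, PsaG) were found only on another chromosome. Lists by keyword (such as peroxidases or laccases) could not be built and are not analysed here. The loci listed for IAA5 and PUL are not analysed here.

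The fit was tested on simulated data with 200 of 19184 genes changed. For double-KO against WT it recovered 93.9% of 4-fold, 35.8% of 2-fold and 1.5% of 1.5-fold changes, with 4 false calls. For the interaction it recovered 48.5% of 4-fold and 3% of 2-fold changes. The simulated noise was independent between genes and few genes changed, so these rates need not hold for the real libraries. Among 100 random lists of 14 genes, camera's preset correlation gave p under 0.05 for 2 in double-KO against WT. Random genes are not chosen to vary together, so this does not test the preset correlation for the real lists. Their estimated correlation was 0.33 for starch, 0.6 for photosynthesis and 0.98 for the secondary wall cellulose synthases. The overlap of comparisons that share the WT libraries was set beside 100 simulations of unchanged groups. The alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, the replicate number as a block, a fit of only the compared groups, a fold of at least 2, and leaving out each library in turn. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for depth, reference matching and figures.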

Results

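Messenger RNA was measured in culms, the jointed stems of rice, at the heading stage. The series title concerns the brittle culm of a double mutant of TAC4 and TAC4L, and the design compared WT, TAC4-KO, TAC4L-KO and double-KO lines of the cultivar Zhonghua 11, with 3 libraries each. Depth inferred from the FPKM values was 9.8, 20.9 and 21.0 M fragments (M, mega) in WT replicates 1 to 3, 17.1, 17.1 and 21.6 M in TAC4-KO, 13.2, 15.6 and 17.1 M in TAC4L-KO, and 15.4, 25.2 and 15.5 M in double-KO. Between 24717 and 26972 genes had a value above 0, and the 10 highest genes took 5.76% to 10.7% of a library's FPKM total. No 2 of the 12 libraries held identical values (66 pairs compared).

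The transcript of TAC4 (LOC_Os02g25230) was higher, not lower, in the libraries labelled as lacking it. It stood at 5.89 ± 1.3 FPKM in WT (SD, n = 3), 8.8 ± 0.89 in TAC4L-KO, 11.4 ± 2.2 in TAC4-KO and 15 ± 1.7 in double-KO. Against WT, TAC4 rose in TAC4-KO (log2 change 0.85, SE 0.19, limma adjusted p = 0.0062) and in double-KO (1.23, SE 0.19, limma adjusted p = 0.00041), and the change in TAC4L-KO missed the threshold (0.52, limma adjusted p = 0.1). The highest WT library (7.32 FPKM) lay below the lowest TAC4-KO library (9.13 FPKM) and the lowest TAC4L-KO library (8.22 FPKM). An exact permutation test gave p = 0.1 for TAC4-KO, double-KO and TAC4L-KO alike, the smallest that 3 against 3 libraries allow. TAC4L (LOC_Os04g19140) was low everywhere, at 0.88, 0.45 and 0.8 FPKM in WT, 0.34, 0.52 and 0.28 in TAC4-KO, 0.64, 0.65 and 0.31 in TAC4L-KO, and 0.53, 0.38 and 0.39 in double-KO. It fell under the expression filter. Without a filter its changes against WT were -0.31, -0.16 and -0.25 in TAC4-KO, TAC4L-KO and double-KO, with limma adjusted p = 0.1, 0.48 and 0.16. The FPKM of a whole gene does not show an edit that leaves the transcript in place, so neither gene checks the labels, and for TAC4 the level goes against the word knockdown in the genotype field. Groups are named here by their labels.

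The ranges of the groups did not overlap along the first principal component (52.8% of the variance of the tested genes). WT lay at -90.5 to -74.8, TAC4L-KO at -51.5, -36 and 5.76, TAC4-KO at 9.91 to 45.9, and double-KO at 76.9 to 80.4. Correlations of log2 values across genes, which are not independent replicates, were 0.968 to 0.975 between double-KO libraries and 0.911 to 0.957 between WT libraries. Between WT and double-KO they were 0.75 to 0.812. TAC4L-KO replicates spanned a wide range, from near WT to near TAC4-KO. They correlated at 0.803 to 0.959 with WT libraries and at 0.889 to 0.958 with TAC4-KO libraries. The closest of these pairs were thus as alike as replicates of WT.

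**Figure D1:**
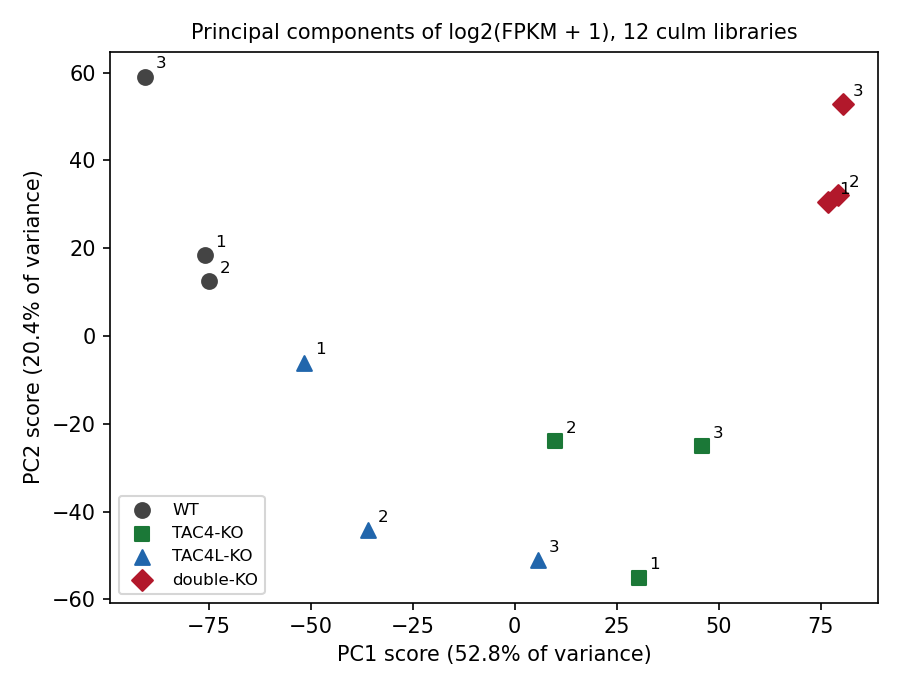
Scores of the 12 culm libraries on the first and second principal components of log2(FPKM + 1) over the tested genes, with each point 1 library, its colour and shape the group, and its number the replicate. WT sits at -90.5 to -74.8 on the first component and double-KO at 76.9 to 80.4, with the single mutants between them.

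Of 19184 genes tested, 9090 (47.4%) differed between double-KO and WT, 6693 (34.9%) between TAC4-KO and WT, and 1378 (7.18%) between TAC4L-KO and WT (limma, adjusted p under 0.05). With a fold of at least 2 these became 5139, 3619 and 906. How the calls divided into higher and lower depended on the scaling between libraries. In double-KO against WT, 57.6% of calls were lower as deposited, 51% under median-of-ratios scaling and 44.4% under quantile normalization. In double-KO against TAC4-KO these shares were 67.5%, 51.2% and 47.2%, and in double-KO against TAC4L-KO 66.9%, 48.2% and 45.1%. In TAC4L-KO against WT they were 48.8%, 64.8% and 51.5%, in TAC4-KO against TAC4L-KO 44.9%, 34.8% and 38.7%, and for the interaction 72.7%, 50.2% and 54.2%. The median log2 change of all tested genes was -0.1 in double-KO against WT as deposited and 0.08 after quantile normalization, -0.2 and 0.03 in double-KO against TAC4L-KO, -0.12 and 0.05 in double-KO against TAC4-KO, 0.1 and 0.06 in TAC4L-KO against WT (-0.01 under median-of-ratios scaling), and -0.19 and 0.02 for the interaction.

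**Figure D2:**
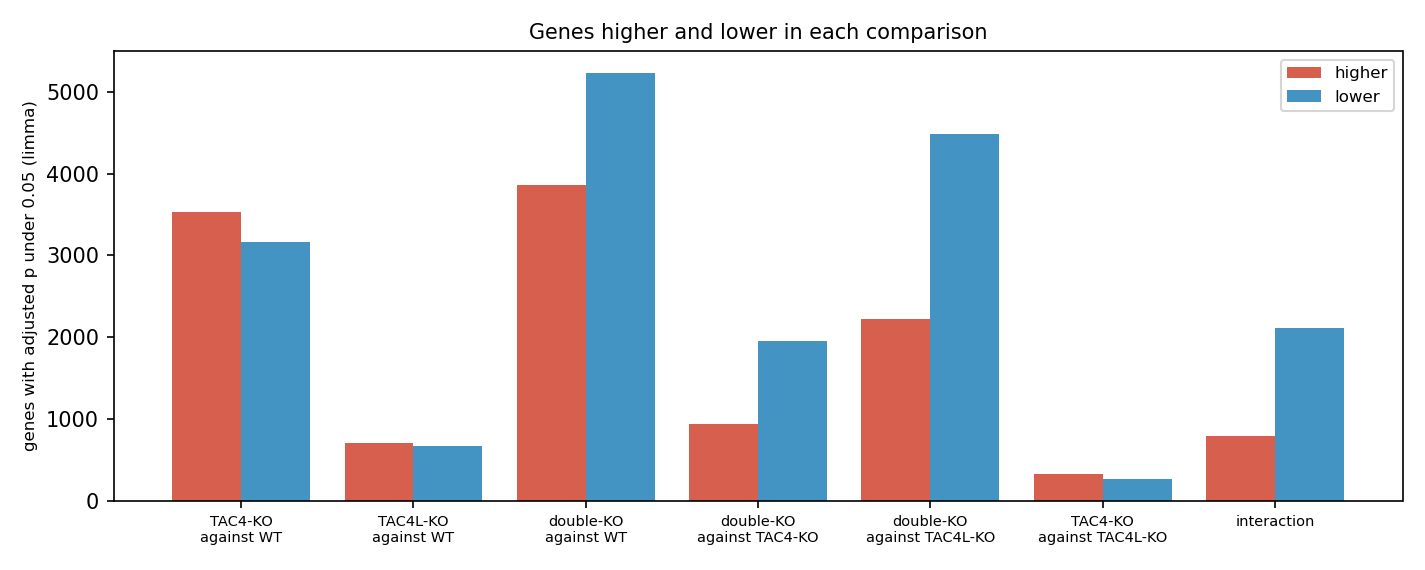
Number of genes higher (red bars) and lower (blue bars) in each of the 7 comparisons at a limma adjusted p under 0.05, with FPKM as deposited and the vertical axis from 0. Double-KO against WT has the most, 3857 higher and 5233 lower, a share of lower calls of 57.6% that becomes 44.4% after quantile normalization.

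The double-KO against WT comparison concerns the line whose brittle culm the series title names, though no measure of brittleness was among the data used here. The 3 cellulose synthases of the secondary wall, the thickened layer that gives the culm its strength, fell together in the libraries labelled double-KO. OsCESA4 (LOC_Os01g54620) went from 260 ± 73.1 FPKM in WT to 27.8 ± 10.9 in double-KO (SD, n = 3 each), OsCESA7 (LOC_Os10g32980) from 282 ± 76.2 to 15 ± 5.9, and OsCESA9 (LOC_Os09g25490) from 286 ± 76.2 to 28.2 ± 12.4. These are log2 changes of -3.23 (SE 0.4), -4.19 (SE 0.4) and -3.37 (SE 0.43), with limma adjusted p of 0.00011, 2.6e-05 and 0.00012. The highest double-KO library for OsCESA4 (37.1 FPKM) lay far below the lowest WT library (192 FPKM). The call held for all 3 genes over all genes tested and adjusted over the list alone. The list stood apart from other genes in camera (adjusted p = 0.014, and adjusted p = 0.51 with an estimated correlation), and its members moved one way in fry (adjusted p = 0.00047).

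**Figure D3:**
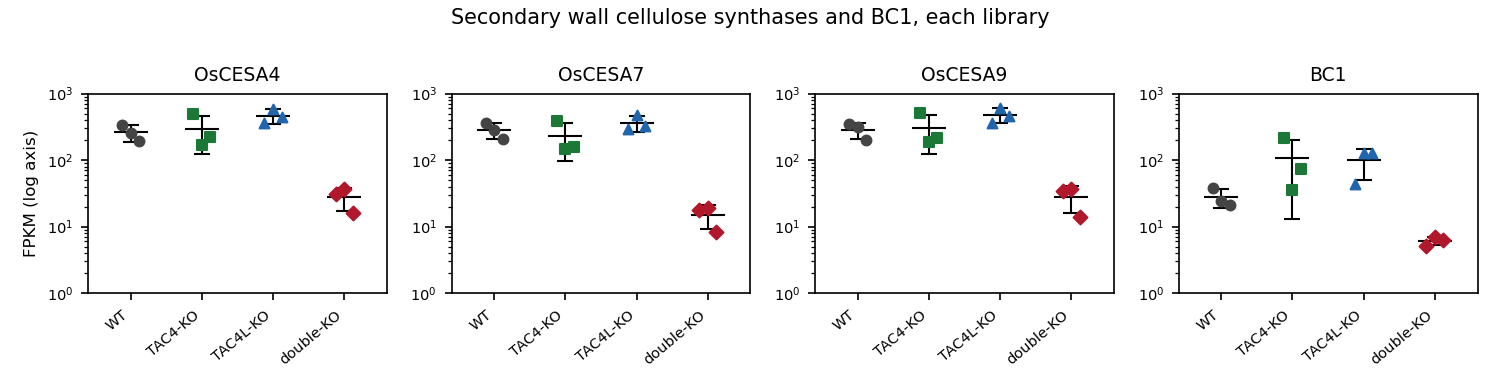
FPKM on a log axis of OsCESA4, OsCESA7, OsCESA9 and BC1 in each library, with the horizontal bar the group mean and the error bar the SD of 3 libraries. All double-KO libraries lie below all WT libraries, with OsCESA4 at 15.8 to 37.1 FPKM in double-KO and 192 to 338 in WT.

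Other wall genes moved less uniformly in the double-KO. BC1 (LOC_Os03g30250), a COBRA-like protein needed for cellulose assembly whose loss makes rice culms brittle, fell from 28 ± 9.25 to 6.11 ± 0.89 FPKM (SD, n = 3; log2 -1.99, SE 0.57, limma adjusted p = 0.013). OsMYB103L, a regulator of cellulose synthesis genes, fell by 1.58 on the log2 scale (SE 0.47, limma adjusted p = 0.017), a call lost under quantile normalization and without WT replicate 1. Among the 8 brittle culm genes BC3 rose (1.14), OsGLU1 fell (-0.7, and -0.45 without WT replicate 1, a call lost under both other scalings and without double-KO replicate 1 or 2 or WT replicate 1 or 2) and BC10, BC12, BC14 and BC15 did not pass (0.02, -0.67, 0.21 and 0.85). That gave 1 higher and 3 lower, and the same counts adjusted over the list alone (camera adjusted p = 0.94, and 0.98 with an estimated correlation). Of the 5 tested regulators of the secondary wall, OsSWN2, a NAC switch, fell (-1.6, SE 0.28, limma adjusted p = 0.0008) together with OsMYB103L, whereas OsSWN1, OsMYB61 and OsMYB58/63 did not pass (-0.64, -0.73 and -1.01). The count was 2 lower over all genes and 4 lower adjusted over the list alone (camera adjusted p = 0.1, and 0.51 with an estimated correlation). Fry gave adjusted p = 0.0092 for the regulators, toward lower. Of the cellulose synthases of the primary wall, 3 of 6 were called, all higher, and the list did not stand apart in camera: OsCESA8 rose from 80.1 ± 15.4 to 392 ± 159 FPKM (2.21, SE 0.39), OsCESA3 by 1.01 (SE 0.2) and OsCESA1 by 1.27 (SE 0.42), with limma adjusted p of 0.00089, 0.002 and 0.026. OsCESA1 lost its call without double-KO replicate 2 (log2 0.83) or WT replicate 2. The count was the same adjusted over the list alone (camera adjusted p = 0.066, and 0.51 with an estimated correlation, and fry adjusted p = 0.022).

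Lignin and xylan genes split in both directions. Of 24 tested lignin genes, 5 were higher and 6 lower, the same adjusted over the list alone (camera adjusted p = 0.94). The calls of C4H LOC_Os01g60450, C4H LOC_Os02g26810, CCoAOMT LOC_Os09g30360 and PAL LOC_Os04g43760 were lost without double-KO replicate 2. C4H LOC_Os02g26810, at 0.92, 2.07 and 21.08 FPKM in WT replicates 1 to 3, was also lost without double-KO replicate 1 or 3. PAL LOC_Os02g41650 lost its call without double-KO replicate 1 or 3 or WT replicate 1. F5H, which adds the hydroxyl group of syringyl lignin, fell from 14.6 ± 3.92 to 0.659 ± 0.201 FPKM (log2 -3.21, SE 0.41, limma adjusted p = 0.00012), and 4CL5 fell (-3.59, SE 0.74, limma adjusted p = 0.0023), while HCT (LOC_Os04g42250) and CCoAOMT (LOC_Os06g06980) rose by 1.18 and 1.4. The WT level of 4CL5 rested on 7.13, 8.68 and 43.1 FPKM, the last in WT replicate 3. Of 8 genes for xylan and mixed-linkage glucan, 1 was higher (IRX9, 1.24) and 2 lower (IRX9L, -0.92, and XAT2, -1.76), with 1 and 1 adjusted over the list alone (camera adjusted p = 0.89). XAT2 lost its call under both other scalings and without any 1 of the double-KO libraries or WT replicate 3 (log2 -1.12 without the last).

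Starch synthesis genes rose in the double-KO. AGPL1 (LOC_Os05g50380), a large subunit of the enzyme that makes ADP-glucose, went from 50.5 ± 14.5 FPKM in WT to 6330 ± 379 in double-KO (SD, n = 3; log2 6.98, SE 0.48, limma adjusted p = 5.2e-06). GBSSII (LOC_Os07g22930), a granule-bound starch synthase, went from 37.6 ± 5.07 to 1690 ± 275 (log2 5.45, SE 0.4, limma adjusted p = 6.7e-06). SSI rose by 3.8 (SE 0.34) and the branching enzyme BEI by 3.01 (SE 0.23), with limma adjusted p of 1.9e-05 and 8.2e-06. In all, 12 of 14 tested members were higher and 0 lower, and adjusted over the list alone 13 were higher and 1 lower (camera adjusted p = 3.9e-07, and adjusted p = 0.51 with an estimated correlation). Of the 12, AGPS1 lost its call without double-KO replicate 1 or 2 or WT replicate 2 or 3, SSIIIa without double-KO replicate 1 or 2 or WT replicate 1 or 3, and ISA1 without double-KO replicate 2.

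Markers of green tissue rose alongside the starch genes. Of 27 photosynthesis genes, 18 were higher and 1 lower in double-KO (19 and 1 adjusted over the list alone), with camera adjusted p = 9.5e-07 and adjusted p = 0.51 with an estimated correlation. The list median was 1.34, and 0.85 without WT replicate 3. The light-harvesting gene LOC_Os01g52240 went from 159 ± 96.2 to 3190 ± 193 FPKM (log2 4.58, SE 0.45, limma adjusted p = 3e-05), and PsaE, a photosystem I subunit, rose by 2.72 (SE 0.28, limma adjusted p = 3.8e-05). The most abundant member, the Rubisco small subunit gene LOC_Os12g19381, fell from 5400 ± 1960 to 2640 ± 694 FPKM (log2 -0.99, SE 0.31, limma adjusted p = 0.019), a call lost without WT replicate 1 or 2 or double-KO replicate 3.

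**Figure D4:**
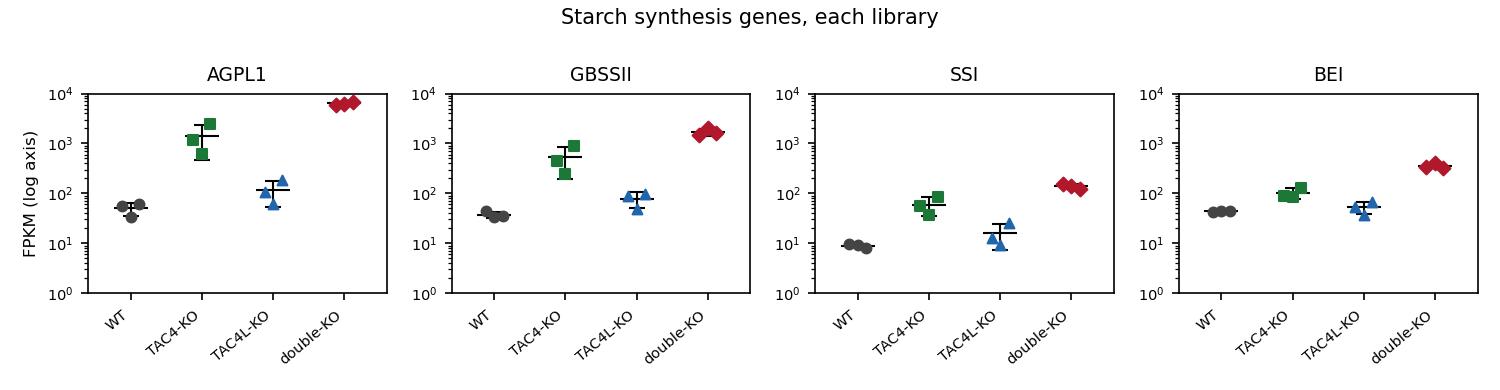
FPKM on a log axis of AGPL1, GBSSII, SSI and BEI in each library, with the horizontal bar the group mean and the error bar the SD of 3 libraries. AGPL1 averages 50.5 FPKM in WT, 117 in TAC4L-KO, 1420 in TAC4-KO and 6330 in double-KO.

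Auxin-responsive genes fell more often than they rose in the double-KO. Of 25 tested Aux/IAA and GH3 genes, 14 were lower and 3 higher (14 and 4 adjusted over the list alone). IAA30 (LOC_Os12g40890) went from 60.4 ± 7.5 to 6.44 ± 2.3 FPKM and IAA31 (LOC_Os12g40900) from 45.5 ± 9.09 to 5.38 ± 1.66 (SD, n = 3), log2 changes of -3.08 (SE 0.27) and -2.88 (SE 0.26) with limma adjusted p of 1.7e-05 and 2e-05. IAA12 fell by 2.74 (SE 0.32, limma adjusted p = 8.1e-05), while IAA4 and IAA21 rose by 1.32 and 1.04. Camera gave an adjusted p = 0.029 for the list, and adjusted p = 0.51 with an estimated correlation. Without WT replicate 1 or double-KO replicate 3 the camera adjusted p was 0.091 or 0.069, and with a filter at 5 FPKM 0.077. IAA4 lost its call without double-KO replicate 1 or 2 or WT replicate 3. So did IAA1 without double-KO replicate 3 or WT replicate 1 or 3, and under median-of-ratios scaling. IAA13 lost its call without double-KO replicate 1 or 2 or WT replicate 2 or 3. IAA2 lost its call without double-KO replicate 2 or WT replicate 2, and IAA19 without double-KO replicate 3 or WT replicate 3.

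The gibberellin and tiller angle lists did not stand apart in camera in the double-KO, though single members were called. Fry called both lists, toward lower (adjusted p = 0.0036 and 0.00055). Of 11 tested gibberellin genes, 2 were higher and 7 lower in double-KO (2 and 8 adjusted over the list alone, with camera adjusted p = 0.18). Of the 7, D18, GA2ox1, KAO and KO2 lost their calls without WT replicate 2, and D18 and GA2ox1 also under quantile normalization. The receptor gene GID1 fell from 134 ± 18.5 to 55.2 ± 7.21 FPKM (log2 -1.26, SE 0.18, limma adjusted p = 0.00028) and CPS1, the first committed step of synthesis, from 6.29 ± 1.42 to 0.83 ± 0.762 (-2.05, SE 0.34, limma adjusted p = 0.00062), while GA20ox1 rose by 1.65 (0.98 without double-KO replicate 3) and SD1 by 0.88. Of 5 tested tiller angle genes, 1 was higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.39). LAZY1 (LOC_Os11g29840), which acts in gravitropism, stood at 6.1 ± 0.053 FPKM in WT and 0.0705 ± 0.0443 in double-KO (-2.73, SE 0.23, limma adjusted p = 1.4e-05), and WOX11 fell by 2.42 (SE 0.32, limma adjusted p = 0.00015). TAC1, which widens tiller angle, rose by 1.58 (SE 0.25, limma adjusted p = 0.00046).

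The jasmonate list did not pass in camera in the double-KO, and the WT levels of its members varied widely. Of 8 tested jasmonate genes, 6 were lower and 0 higher, the same adjusted over the list alone (camera adjusted p = 0.052, and 0.54 with an estimated correlation). Fry gave adjusted p = 0.021 for the list, toward lower. TIFY11d (LOC_Os10g25290) stood at 61.3, 66 and 155 FPKM in WT and at 1.45 ± 0.397 in double-KO (SD, n = 3; log2 -5.16, SE 0.92, limma adjusted p = 0.00096), and TIFY11c at 6.51, 10.6 and 75.1 FPKM in WT and 0.118 ± 0.0501 in double-KO (-4.07, SE 0.81, limma adjusted p = 0.0018). The highest WT value was that of replicate 3 for both. TIFY11e fell by 3.28 (SE 0.74, limma adjusted p = 0.0039). TIFY10b and TIFY11b lost their calls without WT replicate 1 or 3 or double-KO replicate 1 or 3, and TIFY10b also under median-of-ratios scaling.

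The remaining lists showed smaller or single changes in double-KO against WT. LIP9 (LOC_Os02g44870), a dehydrin of dehydration and abscisic acid response, fell from 1260 ± 408 to 40 ± 5.63 FPKM (log2 -4.9, SE 0.56, limma adjusted p = 6.4e-05), and SALT fell by 2.88 (limma adjusted p = 0.0034). No other gene of that list of 7 passed the filter, so it had no set test. Of 4 tested floral MADS-box genes, 3 were higher (MADS16 by 1.85, SE 0.22, limma adjusted p = 8.1e-05), the same adjusted over the list alone (camera adjusted p = 0.074), and each of the 9 untested members averaged under 1 FPKM in every group. Of 5 phloem genes, SUS1 rose by 1.75, SUT2 fell by 1.12 and SWEET14 by 1.51 (1 higher and 2 lower, the same adjusted over the list alone; camera adjusted p = 0.76). SUS1 lost its call without double-KO replicate 2 or 3 or WT replicate 2, and SWEET14 without double-KO replicate 1 or 2 or WT replicate 1 or 2. In fry the MADS-box list moved toward higher (adjusted p = 0.0063) and the phloem list toward lower (adjusted p = 0.0081). Of 5 cell division genes, OSH15 fell by 0.83 (the 1 call adjusted over the list alone too; camera adjusted p = 0.98), a call lost without double-KO replicate 3 or WT replicate 2. Of 4 reference genes, limma called 0, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.94, fry 1), and the list median was 0.02 as deposited and -0.02 after quantile normalization. Of 7 defence genes, PBZ1 and WRKY45 were tested and did not pass (0.02 and 0.28), and 0 of 8 diterpenoid genes passed the filter. Beyond the lists, LOC_Os09g36680 rose from 0.0294 FPKM in WT to 3360 in double-KO (log2 11.41, limma adjusted p = 1.6e-07). LOC_Os06g21369, listed at 0 in every WT library, averaged 136 FPKM. LOC_Os08g24200 fell from 585 to 1.35 FPKM and LOC_Os05g37060 from 278 to 0.959.

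The line labelled TAC4-KO was compared with WT. In the libraries labelled TAC4-KO, photosynthesis and starch genes rose and the secondary wall cellulose synthases showed no called change. LOC_Os01g52240, of the light-harvesting family, went from 159 ± 96.2 to 5000 ± 453 FPKM (SD, n = 3; log2 5.22, SE 0.45, limma adjusted p = 0.00011), and 23 of 27 photosynthesis genes were higher (25 adjusted over the list alone; camera adjusted p = 1e-10, and adjusted p = 0.57 with an estimated correlation). Of 14 starch genes 9 were higher, the same adjusted over the list alone, among them AGPL1 (4.6, SE 0.48), GBSSII (3.59, SE 0.4) and SSI (2.52, SE 0.34), with limma adjusted p of 0.00025, 0.00029 and 0.00062 (camera adjusted p = 0.00012, and adjusted p = 0.57 with an estimated correlation). BEIIa lost its call without TAC4-KO replicate 1 or 3 or any 1 WT library, and ISA1 without TAC4-KO replicate 3. Among the photosynthesis calls, PsbO was lost without TAC4-KO replicate 3 and under quantile normalization. PsbQ and the Rubisco small subunit gene LOC_Os12g17600 were lost without TAC4-KO replicate 2 or 3 or WT replicate 3. LOC_Os12g19470, of the same family, was lost without TAC4-KO replicate 1 or WT replicate 3. OsCESA4, OsCESA7 and OsCESA9 averaged 293 ± 170, 229 ± 132 and 302 ± 177 FPKM, log2 changes of 0.06, -0.41 and -0.03 (limma adjusted p = 0.93, 0.44 and 0.96; camera adjusted p = 0.76 for the list).

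Some wall genes rose in TAC4-KO and others did not pass. OsCESA8 rose by 2.26 (SE 0.39), OsCESA3 by 1.24 (SE 0.2), OsCESA1 by 1.56 (SE 0.42) and OsCESA2 by 0.69 (SE 0.18), with limma adjusted p of 0.0018, 0.0015, 0.014 and 0.012. That was 4 of 6 primary wall genes (5 adjusted over the list alone), with camera adjusted p = 0.018 (adjusted p = 0.57 with an estimated correlation, and 0.087 without WT replicate 2). OsCESA1 lost its call without TAC4-KO replicate 1 or 3 or WT replicate 2, and OsCESA2 without TAC4-KO replicate 1. Of the brittle culm genes, BC3 rose by 1.56, BC15 by 1.67, BC10 by 0.89 and BC1 by 1.57, and OsGLU1 fell by 0.81, a call lost without TAC4-KO replicate 3 or WT replicate 1 (4 higher and 1 lower, the same adjusted over the list alone; camera adjusted p = 0.17). BC12, BC14 and OsMYB103L did not pass (0.09, 0.36 and 0.43). In fry the brittle culm list moved toward higher (adjusted p = 0.041). BC1 stood at 214, 35.1 and 73 FPKM in the 3 libraries, with a limma adjusted p just under the threshold (0.05 as rounded). Its log2 change was 0.88 without TAC4-KO replicate 1. Its call was lost under both other scalings, and without any 1 of TAC4-KO replicates 1 and 3 and the 3 WT libraries. The call of BC10 was lost without TAC4-KO replicate 1 or 3 or WT replicate 1. Among the regulators OsSWN1 rose by 1.26 and OsMYB58/63 by 1.56 (2 of 5, the same adjusted over the list alone; camera adjusted p = 0.54), while OsSWN2 and OsMYB61 did not pass (-0.29 and -0.41). OsMYB58/63 lost its call without TAC4-KO replicate 3 or WT replicate 2. Lignin genes were 8 higher and 2 lower of 24 (10 and 3 adjusted over the list alone), among them CCoAOMT LOC_Os06g06980 (2.07, SE 0.25, limma adjusted p = 0.00041). Among the lower, 4CL5 fell by 2.71, a call lost without TAC4-KO replicate 1 or 3 or WT replicate 3. The camera adjusted p of 0.049 became 0.57 with an estimated correlation, 0.073 after quantile normalization, 0.14 with no filter, 0.097 with a filter at 5 FPKM, 0.054 with the replicate number as a block, and 0.36 or 0.054 without WT replicate 2 or TAC4-KO replicate 3.

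Of the remaining lists in TAC4-KO, camera with the preset correlation called only the jasmonate genes. Fry called the tiller angle list, toward lower (adjusted p = 0.0076). GA2ox3, which inactivates gibberellin, fell from 104 ± 17.9 to 12.7 ± 11.8 FPKM (log2 -3.25, SE 0.58, limma adjusted p = 0.0021), GID1 fell by 1.32 and SD1 rose by 1.77 (limma adjusted p = 0.00071 and 0.00062), for 1 higher and 4 lower of 11, the same adjusted over the list alone (camera adjusted p = 0.28). Of the 4 lower, KAO and KO2 lost their calls without TAC4-KO replicate 3 or WT replicate 2. LAZY1 fell by 2.09 and WOX11 by 2.07, and TAC1 rose by 1.13, with limma adjusted p of 0.00029, 0.0011 and 0.0059 (1 higher and 2 lower of 5, the same adjusted over the list alone; camera adjusted p = 0.43). Auxin-responsive genes were 7 higher and 6 lower of 25, the same adjusted over the list alone (camera adjusted p = 0.64), with IAA4 (2.3), IAA13 (1.91), IAA14 (1.46) and IAA21 (1.44) among the higher and IAA6 (-2.17), GH3-8 (-1.97, lost without TAC4-KO replicate 1 or WT replicate 3), IAA30 (-1.96) and IAA18 (-1.92) among the lower. TIFY11d, TIFY11c and TIFY11e fell by 4.68, 3.74 and 3.06 (3 of 8 lower, the same adjusted over the list alone; camera adjusted p = 0.018, adjusted p = 0.57 with an estimated correlation, and 0.066 without WT replicate 3; fry adjusted p = 0.06). SUS1 rose by 2.26 and SUT2 fell by 0.94, the 2 called of 5 phloem genes also over the list alone (camera adjusted p = 0.72, with a median of -0.33 and a mean of 0.12). MADS14 rose by 0.59, the 1 called MADS-box gene over all genes and over the list alone (camera adjusted p = 0.38), a call lost under median-of-ratios scaling and without TAC4-KO replicate 2 or 3 or WT replicate 3 (log2 0.39 without the last). LIP9 fell by 1.68 and SALT by 2.27. Both lost their calls without TAC4-KO replicate 1 or 3 or WT replicate 3, and LIP9 also without WT replicate 1 or 2. IRX9 rose by 1.33, the 1 called of 8 xylan genes, also over the list alone (camera adjusted p = 0.45). Of the reference genes EF1a fell, a call lost without TAC4-KO replicate 1 or WT replicate 1 (camera adjusted p = 0.45). Beyond the lists, LOC_Os09g10010 fell from 548 to 4.47 FPKM and LOC_Os08g37660 from 129 to 0.901. Of all 6693 calls, 3528 were higher and 3165 lower, and 4334 genes were called without TAC4-KO replicate 3.

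Fewer genes changed in the line labelled TAC4L-KO. In the libraries labelled TAC4L-KO, the secondary wall cellulose synthases averaged 465 ± 116, 361 ± 94.5 and 476 ± 120 FPKM for OsCESA4, OsCESA7 and OsCESA9 (SD, n = 3), and none passed (log2 0.84, 0.36 and 0.74, limma adjusted p = 0.19, 0.57 and 0.27; camera adjusted p = 0.44 for the list). OsCESA3 rose from 95.8 ± 6.91 to 227 ± 60.4 FPKM (1.2, SE 0.2, limma adjusted p = 0.012) and OsCESA2 by 0.79 (SE 0.18, limma adjusted p = 0.029), for 2 of 6 primary wall genes (3 adjusted over the list alone; camera adjusted p = 0.1). BC3 rose by 0.99 (limma adjusted p = 0.03), the 1 called of 8 brittle culm genes (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.36), and BC1 averaged 98.7 ± 48.2 FPKM without passing (1.67, limma adjusted p = 0.084). BC10, BC12, BC14, BC15, OsMYB103L and OsGLU1 did not pass (0.64, 0.56, -0.01, 0.91, 0.49 and -0.79), nor did the regulators OsSWN1, OsSWN2, OsMYB61 and OsMYB58/63 (0.59, 0.42, 0.2 and 0.14; camera adjusted p = 0.49). LAZY1 fell to 2.12 ± 0.821 FPKM (-1.23, SE 0.23, limma adjusted p = 0.018), the 1 called of 5 tiller angle genes (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.57, toward lower, with a median of 0.23 and a mean of -0.17).

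No starch gene (0 of 14) and no photosynthesis gene (0 of 27) was called in TAC4L-KO, also when adjusted over the list alone, with list medians of 0.5 and 0.46 (limma, with 4 genes of each list at an unadjusted p under 0.05; camera adjusted p = 0.27 and 0.1, fry 0.29 and 0.32). Of the jasmonate genes, TIFY11d fell by 3.63 (SE 0.92) and TIFY10a by 1.67 (SE 0.42), with limma adjusted p of 0.039 and 0.038. That was 2 of 8 over all genes and 7 adjusted over the list alone (camera adjusted p = 7.7e-05, adjusted p = 0.74 with an estimated correlation, and fry adjusted p = 0.18). TIFY11d stood at 45.9 FPKM in TAC4L-KO replicate 1 and at 2.72 and 0.97 in the other libraries. Among auxin-responsive genes IAA4 rose by 2.04 and IAA23 by 0.99, and IAA30 fell by 1.23 and GH3-8 by 2.41, for 2 higher and 2 lower of 25 (6 and 2 adjusted over the list alone; camera adjusted p = 0.49). No lignin, xylan, gibberellin, phloem or cell division gene was called by limma over all genes or adjusted over the list alone, with 9, 2, 3, 1 and 0 genes at an unadjusted p under 0.05 (camera adjusted p = 0.44, 0.57, 0.61, 0.85 and 0.57). Camera placed the lignin and phloem lists toward lower although their medians were 0.04 and 0.15 (means -0.38 and 0.11). No MADS-box or reference gene was called over all genes (0.42 and 0.44), and 2 MADS-box genes were higher adjusted over the list alone. Beyond the lists, LOC_Os06g13700 rose from 1.28 to 60.7 FPKM and LOC_Os03g06430 from 0.655 to 16.2, and LOC_Os01g21250 fell from 414 to 20.1 FPKM and LOC_Os04g32920 from 236 to 8.83. The 1378 calls (706 higher, 672 lower) rested on few libraries. Leaving out TAC4L-KO replicate 3 left 135, TAC4L-KO replicate 2 left 139, WT replicate 3 left 364, WT replicate 1 left 892, and without TAC4L-KO replicate 1 there were 2168. The calls of TIFY11d, TIFY10a, GH3-8, BC3 and IAA30 were each lost without TAC4L-KO replicate 2 or 3 or WT replicate 1 or 3. The calls of OsCESA2 and IAA4 were lost without TAC4L-KO replicate 2 or 3 or WT replicate 3, and that of IAA23 without TAC4L-KO replicate 2 or 3 or WT replicate 2 or 3. OsCESA2 and IAA23 also lost their calls under median-of-ratios scaling. LAZY1 lost its call with a pseudocount of 0.1 and without TAC4L-KO replicate 3, and OsCESA3 without TAC4L-KO replicate 2. With only the TAC4L-KO and WT libraries in the fit, 32 genes were called, and all 10 list genes called in TAC4L-KO lost their call.

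Set directly against each other, the single mutants differed in starch and photosynthesis genes. TAC4-KO exceeded TAC4L-KO for AGPL1 (log2 3.51), GBSSII (2.6) and SSI (1.87), with limma adjusted p of 0.0073, 0.011 and 0.018, and 6 of 14 starch genes and 13 of 27 photosynthesis genes were higher (7 and 23 adjusted over the list alone). Camera gave adjusted p = 1.4e-07 and 3.4e-19 for these lists, and adjusted p = 0.21 for both with an estimated correlation. Of 11 gibberellin genes SD1 was higher by 1.15 and GID1 lower by -1.09 on the log2 scale (limma adjusted p = 0.029 and 0.014), with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.23, fry 0.075). Of 24 lignin genes 3 were higher (10 adjusted over the list alone; camera adjusted p = 1e-06, and 0.21 with an estimated correlation). IAA6 and IAA18 were lower by -1.75 and -1.52, the 2 called of 25 auxin-responsive genes, also over the list alone (limma adjusted p = 0.048 and 0.039; camera adjusted p = 0.92). The secondary wall cellulose synthases did not pass (log2 -0.79, -0.77 and -0.77; camera adjusted p = 0.23), nor did any brittle culm gene or regulator over all genes, and 1 regulator was higher adjusted over the list alone (camera adjusted p = 0.33 and 0.9). The 584 calls (322 higher, 262 lower) became 38, 94 and 1361 without TAC4L-KO replicates 2, 1 and 3, and 58 and 255 without TAC4-KO replicates 3 and 1.

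Against either single mutant, the double-KO was lower for the secondary wall cellulose genes. OsCESA4, OsCESA7 and OsCESA9 were lower by -3.28, -3.78 and -3.34 on the log2 scale against TAC4-KO (limma adjusted p = 0.00064, 0.00028 and 0.00077) and by -4.07, -4.55 and -4.11 against TAC4L-KO (limma adjusted p = 7.1e-05, 3.4e-05 and 8.4e-05). BC1 was lower by -3.55 and -3.66 (limma adjusted p = 0.0022 and 0.00072), and 3 of 8 brittle culm genes were lower in each comparison (4 and 3 adjusted over the list alone; camera adjusted p = 0.038 and 0.49, and 0.4 and 0.78 with an estimated correlation). Of the 5 regulators 4 were lower in each (4 and 5 adjusted over the list alone; camera adjusted p = 0.0025 and 0.032, and 0.31 and 0.57 with an estimated correlation). For the cellulose synthases camera gave adjusted p = 0.00021 and 0.0016, and 0.31 and 0.57 with an estimated correlation. Starch genes were higher than in TAC4-KO for 7 of 14 members and than in TAC4L-KO for 10 of 14 (9 and 10 adjusted over the list alone; camera adjusted p = 3.2e-06 and 7.7e-09, and 0.31 and 0.33 with an estimated correlation). Photosynthesis genes were 0 higher and 3 lower against TAC4-KO and 12 higher and 1 lower against TAC4L-KO (3 lower, and 13 higher and 1 lower, adjusted over the list alone; camera adjusted p = 0.071 and 1.3e-06, and 0.75 and 0.57 with an estimated correlation). Auxin-responsive genes were lower for 14 of 25 in both comparisons (16 in each adjusted over the list alone; camera adjusted p = 3.2e-06 and 0.00024, and 0.31 and 0.57 with an estimated correlation). Lignin genes were 0 higher and 7 lower of 24 against TAC4-KO (12 lower adjusted over the list alone), and 3 higher and 3 lower against TAC4L-KO. Camera gave the lignin list adjusted p = 0.0025 and 0.49 (0.4 and 0.78 with an estimated correlation), and fry 0.01 and 0.77. Fry also called the gibberellin, tiller angle and phloem lists toward lower against TAC4L-KO (adjusted p = 0.0025, 0.0015 and 0.0065), but not against TAC4-KO (0.084, 0.074 and 0.069). MADS16 was higher by 1.5 and 1.76, SSI by 1.28 and 3.15, PCNA by 1.03 against TAC4-KO and TAC1 by 0.89 against TAC4L-KO, and LIP9 was lower by -3.23 and -4.39. In all, 2883 genes differed from TAC4-KO (937 higher, 1946 lower) and 6714 from TAC4L-KO (2224 higher, 4490 lower). The first count was 1441 without double-KO replicate 3, 1479 without TAC4-KO replicate 1 and 1918 without double-KO replicate 1. The second was 4017 without TAC4L-KO replicate 2 and 4305 without double-KO replicate 3.

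The interaction asks whether the double-KO departs from the sum of the single-mutant changes, and the 3 secondary wall cellulose synthases did so. Its log2 values were -4.13 (SE 0.57) for OsCESA4, -4.14 (SE 0.56) for OsCESA7 and -4.08 (SE 0.6) for OsCESA9, with limma adjusted p of 0.0013, 0.0013 and 0.0019, and -5.23 (SE 0.8, limma adjusted p = 0.0022) for BC1. All 3 cellulose synthases were called over all genes and over the list alone (camera adjusted p = 0.0018, and adjusted p = 0.48 with an estimated correlation). Brittle culm genes were 4 lower of 8 (1 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.026, and adjusted p = 0.48 with an estimated correlation), namely BC1, BC3 (-1.41), BC10 (-1.51) and OsMYB103L (-2.5). The camera adjusted p was 0.063 or 0.071 without double-KO replicate 1 or WT replicate 2, and 0.081 with a filter at 5 FPKM. The regulators were 4 lower of 5, the same adjusted over the list alone: OsSWN1 (-2.49), OsSWN2 (-1.74), OsMYB58/63 (-2.71) and OsMYB103L (camera adjusted p = 0.0082, adjusted p = 0.48 with an estimated correlation, and 0.081 with a filter at 5 FPKM). OsMYB103L lost its call after quantile normalization and without 8 of the 12 libraries each (every one but TAC4L-KO replicate 1, TAC4-KO replicates 2 and 3 and WT replicate 1), and BC10 without TAC4L-KO replicate 2 or TAC4-KO replicate 1.

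Auxin-responsive genes were 1 higher and 12 lower of 25 in the interaction (1 and 16 adjusted over the list alone, with camera adjusted p = 0.00029, and adjusted p = 0.48 with an estimated correlation). A negative interaction is a value below the sum of the single changes, not a fall against WT. In double-KO against WT the photosynthesis and primary wall lists had medians of 1.34 and 0.67, and the jasmonate list -1.8. The calls of IAA1, IAA12, IAA14, IAA17 and IAA21 were lost without double-KO replicate 3. Those of IAA1, IAA17 and IAA21 were also lost under median-of-ratios scaling. IAA24 (-3.36, SE 0.57), IAA23 (-3.25, SE 0.33) and IAA4 (-3.02, SE 0.55) were the lowest, with limma adjusted p of 0.0036, 0.00037 and 0.0051. GH3-8 was higher (3.14, SE 0.83, limma adjusted p = 0.029), a call lost without TAC4L-KO replicate 2 or 3, TAC4-KO replicate 1, or double-KO replicate 2 or 3. IAA23 stood at 17.2 FPKM in WT, 32.1 in TAC4-KO, 34.1 in TAC4L-KO and 5.86 in double-KO. IAA13 was at -2.12. IAA4 was higher than WT in TAC4-KO, TAC4L-KO and double-KO (log2 2.3, 2.04 and 1.32). Lignin genes were 7 lower of 24, with 4CL1 at -2.78 and F5H at -3.34, xylan genes 2 lower of 8 and primary wall genes 2 lower of 6, all the same adjusted over the list alone (camera adjusted p = 0.15, 0.15 and 0.082). Fry gave these lists adjusted p = 0.077, 0.047 and 0.05 (the last as rounded). LIP9 was at -2.71, a call lost under median-of-ratios scaling and without any 1 of TAC4L-KO replicates 1 and 2, TAC4-KO replicates 1 and 2, the double-KO libraries and WT replicates 2 and 3. Photosynthesis genes were 4 lower of 27 (7 adjusted over the list alone; camera adjusted p = 0.0076, adjusted p = 0.67 with an estimated correlation, 0.064 without WT replicate 3, and fry adjusted p = 0.12). Each of the 4 was lost under median-of-ratios scaling and without TAC4-KO replicate 2 or 3, double-KO replicate 1 or 3, or WT replicate 3. Starch genes were 2 higher of 14, AGPS1 (1.12) and BEI (1.61), the same adjusted over the list alone (camera adjusted p = 0.014, adjusted p = 0.54 with an estimated correlation, 0.075 after quantile normalization, 0.052 without TAC4-KO replicate 2, and fry adjusted p = 0.2). The list median was 0.74, and 0.45 and 0.48 without TAC4L-KO replicate 2 and TAC4-KO replicate 2. AGPS1 lost its call without TAC4L-KO replicate 2 or 3, TAC4-KO replicate 1 or 2, double-KO replicate 1 or WT replicate 1. Jasmonate genes had a median of 1.78 with 0 of 8 called by limma and 3 at an unadjusted p under 0.05 (fry adjusted p = 0.2, camera adjusted p = 0.0076, and adjusted p = 0.54 with an estimated correlation). The floor of log2(FPKM + 1) at 0 fixed part of this in advance. TIFY11d changed by -4.68 in TAC4-KO and -3.63 in TAC4L-KO, together more than its WT level on that scale. Its interaction therefore had to be positive, and the camera result decides nothing for genes near that floor. Gibberellin genes were 3 lower of 11 (2 higher and 3 lower adjusted over the list alone), tiller angle genes 1 lower of 5, phloem genes 1 lower of 5, MADS-box genes 1 higher of 4 (MADS16, 1.4), and reference genes 1 higher of 4 (EF1a), the last 4 the same adjusted over the list alone (camera adjusted p = 0.97, 0.83, 0.84, 0.79 and 0.15). Camera placed the tiller angle and MADS-box lists toward higher although their medians were -0.09 and -0.36. Fry gave adjusted p = 0.047 for the reference list. In all, 2894 genes were called (789 higher, 2105 lower). The count was 1478 without TAC4L-KO replicate 2, 1577 without TAC4-KO replicate 1 and 1579 without double-KO replicate 3.

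The single mutants shared changes against WT, in a number that rested on few libraries. Of the genes called in both, 619 were higher and 609 lower in both and 0 went opposite ways, where independent lists of these sizes would share 129.84 and 110.87. The overlap of single-KO effects, 1228 calls, became 126 and 136 without TAC4L-KO replicates 3 and 2, 341 without WT replicate 3, 752 without TAC4-KO replicate 3 and 1874 without TAC4L-KO replicate 1. It was 30 when each single mutant was fitted with WT alone. These alternatives were chosen after the data were seen. The log2 changes correlated across genes at r = 0.82 with a covariance of 0.5. Unchanged groups were simulated as the WT mean plus residuals drawn from libraries of any group, for the WT group too. They gave a mean r of 0.5 (highest 0.9) and a mean covariance of 0.05. Their 0 shared calls were nearly fixed in advance, because unchanged groups give hardly any calls to share. TAC4-KO and double-KO shared 5024 calls in the same direction and 66 in opposite directions (r = 0.81, covariance 0.87), and TAC4L-KO and double-KO 979 and 54 (r = 0.61, covariance 0.46). The 979 became 109 and 119 without TAC4L-KO replicates 3 and 2, 312 without WT replicate 3, 567 and 603 without double-KO replicates 2 and 1, 1526 without TAC4L-KO replicate 1 and 26 with only the compared groups in each fit. The 5024 became 3315 without TAC4-KO replicate 3. Independent lists would share 709.31 higher and 863.35 lower calls in the former pair and 141.94 and 183.31 in the latter. The simulated covariance was 0.05 for both, and the simulated r averaged 0.48 and 0.42, with a highest of 0.9 for each. Shared controls add the same covariance with or without an effect, and the observed covariance less the simulated one was 0.45, 0.82 and 0.41 for the 3 pairs in this order. The simulation drew its spread from all groups, so its covariance does not measure what these 3 WT libraries add. The 3 WT libraries are too few to be split, so part of the excess of shared calls may come from the shared controls.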

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

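The tests of scaling for the cellulose synthases and of the xylan genes, and both permutations of residuals, were chosen only after the result was seen. A difference between groups singled out the following: the change between double-KO and TAC4-KO differed from that between TAC4L-KO and WT for 2894 genes (groups as labelled), by a test of the interaction itself in limma. Among the wall genes the log2 interaction was -4.13 for OsCESA4, -4.14 for OsCESA7, -4.08 for OsCESA9, -5.23 for BC1, -1.41 for BC3, -1.51 for BC10, -2.5 for OsMYB103L, -2.49 for OsSWN1, -1.74 for OsSWN2 and -2.71 for OsMYB58/63. For BC3 and BC10 the double-KO was not below WT (1.14 and 0.02), and both single mutants averaged above WT. OsSWN1 and OsMYB58/63 were lower in the double-KO than in WT without being called. Of 100 groupings of the 12 libraries, only the real 1 gave as many calls, and the highest other gave 244, but regrouping moves the differences between groups into the spread, so this excludes nothing for the interaction. When the residuals around the sum of the single effects were permuted instead, 1 of 100 orders (the real one) gave as many calls and the highest other gave 1, but those residuals hold the interaction itself, which widens the spread, so this decides nothing either. When the residuals within groups, which hold no interaction, were permuted and added to that sum, 1 of 100 (the real data) gave as many calls and the highest other gave 340, which argues against spread within groups as the source of the count, if the libraries are exchangeable. No group had enough libraries for a test of outliers.

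The fall of the 3 secondary wall cellulose synthases in the double-KO was weighed against technical explanations. Under median-of-ratios scaling and quantile normalization the median change, taken at the scaling nearer to 0, was -3.27, which argues against scaling between libraries. The 10 highest genes taking more of the FPKM total would shift all other genes by -0.03 on the log2 scale, far less than the fall. A sampling gradient along the culm stays open: the slope on the starch genes within groups predicted a change of 0.23, with a 95% interval of -4.43 to 4.9 that is too wide to decide. A smaller share of wall-thickening cells cannot be told apart from lower expression per cell, since the 7 xylan synthesis genes had a median of -0.56 but ranged from -1.76 to 1.24. An effect of the labelled genotype on these cells could be the cause and was not tested.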

How the results depend on the processing

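The alternatives were fixed before the data were examined, except 2 for the overlap of single-KO effects, which were chosen after seeing the data. Called genes and lists kept their direction under every alternative run. Medians of lists without a call changed sign with scaling (as deposited, median-of-ratios, quantile): lignin in TAC4L-KO against WT (0.04, -0.07, 0.02), cell division (-0.06, 0.04, 0.12) and reference genes (0.02, 0.12, -0.02) in double-KO against WT, and tiller angle (-0.09, 0.16, 0.18) and gibberellin (-0.01, 0.25, 0.22) in the interaction. Of the single-gene results, 1474 kept their side of the threshold and 143 lost the call across the settings other than leaving out a library, and 1422 and 330 across the latter, and for lists 116 and 30, and 134 and 10. Leaving out 1 library gave 4334 to 6330 calls in TAC4-KO against WT, 135 to 2168 in TAC4L-KO against WT, 7340 to 8755 in double-KO against WT, 1441 to 2372 in double-KO against TAC4-KO, 4017 to 6312 in double-KO against TAC4L-KO, 38 to 1361 in TAC4-KO against TAC4L-KO and 1478 to 3260 for the interaction. An arm left with 2 libraries shares the spread pooled over all groups. A fold of at least 2 left 3619, 906, 5139, 1733 and 3476 calls in the first 5 of these, as its construction requires. A fit of only the compared groups gave 4949, 32, 7708, 3463, 6827 and 74 calls in the first 6, in the same order, and no filter gave 856 in TAC4L-KO against WT and 249 in TAC4-KO against TAC4L-KO, and the cause was not tested. Replicates were less alike in WT and TAC4L-KO (r of 0.911 to 0.957 and 0.927 to 0.963) than in double-KO (0.968 to 0.975). The main fit pools the spread of all groups, so its p-values for TAC4L-KO against WT may be too small. Camera called 17 lists over the 4 main comparisons with the preset correlation and 0 with an estimated one. The overlap of single-KO effects was 1163 shared calls with a pseudocount of 0.1, 1222 under median-of-ratios scaling and 849 with a filter at 5 FPKM. Chosen after seeing the data, leaving out 1 library gave an overlap of 126 to 1874, and a fit of only the compared groups 30. Beyond the losses under scaling, a pseudocount of 0.1 or a left-out library given above, named genes lost their call under 3 other settings. With no filter these were AGPS1, D18, IAA13, OsCESA1, OsGLU1, LOC_Os12g19381, LOC_Os12g17600, SSIIIa, SWEET14, TIFY10b, TIFY11b, XAT2 and C4H LOC_Os02g26810 in double-KO. In TAC4-KO they were BC1, BEIIa, GH3-8, KAO, KO2, LIP9, LOC_Os12g17600, MADS14, OsGLU1, PsbO and PsbQ. In TAC4L-KO they were GH3-8, IAA23, TIFY10a and TIFY11d. In the interaction they were GH3-8, IAA1, IAA12, IAA14, IAA17, IAA21, LIP9, OsMYB103L and the 4 photosynthesis genes. With the replicate number as a block they were IAA1, IAA13, OsGLU1, SSIIIa, TIFY10b and XAT2 in double-KO and BC1, MADS14 and OsGLU1 in TAC4-KO. In TAC4L-KO they were BC3, GH3-8, OsCESA2, TIFY10a and TIFY11d, and in the interaction IAA1, IAA21 and the 4 photosynthesis genes. With only the compared groups they were AGPS1, CCoAOMT LOC_Os09g30360, IAA1, IAA13, OsGLU1, LOC_Os12g19381, LOC_Os12g17600 and SSIIIa in double-KO. In TAC4-KO they were BC1, BC10, BEIIa, EF1a, ISA1, KAO, KO2, LOC_Os12g17600, MADS14, OsGLU1, PsbO and PsbQ, and in TAC4L-KO every called list gene. The replicate numbers of the titles did not pair the libraries: residuals correlated at -0.43 to 0.27 over 18 pairs of the same number (4 above 0.1, mean -0.05, against 0.03 for different numbers), and 2 libraries correlated best with their own number. The library names carry numbers that differ from these in the mutants, and a pairing by them was not examined. With the number as a block, TAC4L-KO against WT had 665 calls and the others 5969, 8522, 2580, 6058, 394 and 2328, and the cause was not tested. TAC4L, below the filter, has a value only without a filter, alternatives for single genes were run for called list genes and TAC4, and set-test totals only for settings that apply to all 4 main comparisons. Depth differed 2.58-fold between libraries, and WT replicate 1 (9.8 M fragments) resolves low genes least.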

Other observations

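The tests of leaf tissue and of departures from additivity were chosen only after the result was seen. LOC_Os09g36680, chosen after its values were seen, averaged 0.0294 FPKM in WT, 0.247 in TAC4-KO, 0 in TAC4L-KO and 3360 in double-KO, and LOC_Os07g10840 averaged 67.9, 5.05, 2.55 and 155 in the same order (log2 interaction 11.22 and 8.54, limma adjusted p = 1e-05 and 0.00031). LOC_Os01g70830 averaged 11.6, 45.9, 79.1 and 0.221 FPKM and LOC_Os01g62480 8.5, 69, 53.1 and 2.27 (log2 interaction -7.19 and -6.95, limma adjusted p = 0.0013 and 0.00016). These identifiers have no name in the sources used here.

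Starch and light-harvesting genes rose together in the double-KO, and technical explanations were weighed. Leaf tissue in the sampled culms stays open: the abundant Rubisco small subunit gene LOC_Os12g19381 changed by -0.99 while light-harvesting genes had a median of 2.26, but the small subunit genes LOC_Os12g17600 and LOC_Os12g19470 were at 1.36 and 0.64 (the latter not called), and LOC_Os12g19381 was already high in WT. LOC_Os12g17600 was at 0.85 without WT replicate 3 and lost its call without it or double-KO replicate 1 or 2, and LOC_Os12g19381 lost its call without WT replicate 1 or 2 or double-KO replicate 3. Under the 2 other scalings the lower median of the starch genes was 2.98, which argues against scaling. A sampling gradient stays open: the main direction of variation within groups correlated with the double-KO changes at an absolute r of 0.36 (rank correlation 0.25) and with the TAC4L-KO and TAC4-KO changes at 0.57 and 0.55, so stage or position along the culm might contribute and cannot be told apart from an effect of the genotype.

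Of 8 tested jasmonate genes, 6 were lower in the double-KO, with WT replicate 3 the highest for TIFY11c and TIFY11d. Leaving out WT replicates 1, 2 and 3 in turn gave medians of -2.18, -2.68 and -2.26 for the tested repressors in double-KO against WT, with 3, 5 and 3 called lower, which argues against a single WT library as the source. Under the 2 other scalings the median nearer to 0 was -2.15. How the plants were handled before sampling is not given in the sources used here and was not tested.

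A hypothesis that genes that fell in the double-KO depart from the sum of the single effects more often than genes that rose stays undecided, since the scaling that centres the interaction also sets the balance. As deposited, 12.9% of 5233 lower genes and 7.8% of 3857 higher genes had a called interaction of the same sign, a ratio of 1.65. Under quantile normalization the ratio was 1.13 and under median-of-ratios scaling 0.84.

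For each comparison of 2 groups, 6 libraries make 10 splits, too few for a share under 0.05, and in each only 1 split, the real one, gave as many calls. Any other split mixes the 2 groups and moves their difference into the spread, so low counts there exclude nothing. The real values and the highest other split were 6693 and 0 for TAC4-KO against WT, 1378 and 0 for TAC4L-KO against WT, 9090 and 0 for double-KO against WT, 2883 and 1 for double-KO against TAC4-KO, 6714 and 1 for double-KO against TAC4L-KO, and 584 and 99 for TAC4-KO against TAC4L-KO.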
